A study of Mus musculus with 5 samples.

How the data were processed

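CUT&RUN for BCLAF1 was done on 50000 sorted cells per library, per the labels' protocols. HSCs were pooled from 24 to 26 embryos. The protocol describes the LSK cells as adult bone marrow pooled from 2 to 3 mice, while the tissue label of the LSK libraries names E17.5 fetal liver, so the age and tissue of the LSK cells are left open. The files are 1 peak list per library in the narrowPeak layout. Genome build mm10 is named in the submitters' processing notes. The aligner, the peak caller, its control and the handling of duplicate reads are not given in the sources used here. The labels do not say whether the 2 HSC WT libraries came from separate pools of embryos, so their spread may be technical.

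Each deposited list gives a fold enrichment per peak, the ratio of reads to the local background, as the authors' caller computed it. It also gives −log10 p-values and −log10 q-values as deposited. The deposited score equals the −log10 q-value times 10, rounded down. The lowest deposited −log10 q-value was above 2 in every list. Enrichments are not scaled between libraries and were used to describe, rank and filter peaks within a list. To choose which regions of 2 lists to name, the mean of their enrichments was used.

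Depth per library is not given in these files. The number of reads over each peak summit was therefore recovered from the deposited values, by solving for the read number and background that give both the fold enrichment, with a pseudocount of 1 on each, and the Poisson p-value. Up to a −log10 p-value of 300, a whole read number fitted both values in 100% of peaks in each list (relative tolerance 0.0001). Only whole numbers were tried. The most common background of a list was taken as that of the genome and as a measure of its depth. Stronger peaks were not resolved in this way. A pseudocount of 1 lowers the enrichment of peaks in shallow libraries. Reads without molecular identifiers are not independent molecules, and all intervals cover counting error only.

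Peaks on chromosomes 1 to 19, X and Y entered the comparisons. Peaks on mitochondrial and unplaced sequences made up 17.8% of HSC WT 1, 13.0% of HSC WT 2, 4.14% of HSC KO, 13.8% of native LSK and 3.81% of fixed LSK peaks. Peaks overlapped when they shared at least 1 bp. Shares have exact (Clopper-Pearson) 95% binomial intervals. Overlaps were compared with 1000 random placements of the peaks of one list on the same chromosome with the same widths (one-sided permutation test), and p-values were adjusted by Benjamini and Hochberg over 20 ordered pairs of lists. Placement did not leave out assembly gaps or repeats, which were not known here, so the shares after random placement are approximate. Peaks in repeats were not left out either. With 1000 placements the smallest p is 0.001 for a one-sided and 0.002 for a two-sided placement test. The test of whole genes with 10 kb on either side used 10000 placements. Tables of peaks were compared with Fisher's exact test, two-sided.

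Gene positions came from an NCBI RefSeq table of mouse assembly GRCm38.p6, the same coordinates as mm10, with 21883 protein-coding genes. It gives no strand, exons or introns. The planned distance to a transcription start was therefore replaced by the distance to either annotated boundary of a gene, so that the 3' end counts as well as the 5' end, and exon or intron is not stated for any region. The 16 gene lists were fixed before the data were examined. Of their members, 527 distinct genes matched the table, counting synonyms. Each list was tested against all protein-coding genes, with adjustment over 80 tests and also over the list alone. One list member near a KO peak is not reported here.

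The genes named were fixed by rule before the data were examined. They are Bclaf1 and Thrap3, the 10 genes with the highest mean enrichment within 1 kb of regions in both HSC WT lists without KO and with KO, the 10 at KO peaks without HSC WT, the 10 in both LSK lists, and the 5 in the native and the 5 in the fixed LSK list alone. Members of the gene lists at a peak in both HSC WT or both LSK lists were also named, at most 15. Where a class held fewer than 5 genes, its 5 strongest regions were named by coordinates. The class of both HSC WT lists without KO held 0 genes and 3 regions in all.

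The scripts were tested on simulated data. All 134 planted overlaps of a simulated HSC WT 1 list with the KO list were found. The planted peaks were copies of KO peaks and the others were placed off them, so this checked counting only. Of 60 random lists of that size, 0 reached a placement p of 0.05. Few overlaps arise by chance and this p moves in coarse steps, so its error rate was not measured. Of 1200 simulated read numbers, 1200 were recovered. Alternatives fixed before the data were examined were another overlap rule, a distance of 500 bp, a −log10 q-value of at least 5, lists of equal size (447 peaks for comparisons with HSC lists, 278 between the LSK lists and for gene positions), all sequences, leaving out regions called in all 5 lists, a placement that keeps the share near genes, leaving out each HSC WT library, and distances of 5 kb and 200 bp from genes. Others were chosen after seeing the data and are named as such. Alternatives used 200 placements for overlaps. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.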

Results

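Binding of BCLAF1, a nuclear protein linked to transcription and RNA splicing, was profiled in mouse blood stem and progenitor cells by CUT&RUN. In this assay an antibody directs a nuclease to chromatin, and the DNA fragments it releases are sequenced. All 5 libraries were made with the same anti-BCLAF1 antibody. Haematopoietic stem cells (HSCs) came from fetal liver at embryonic stage E17.5, with 2 wild-type (WT) libraries and 1 knockout (KO) library. Lineage-negative, Sca1-positive and Kit-positive (LSK) progenitors gave 1 library from native cells and 1 from cells fixed with 0.1% formaldehyde for 2 min. The KO library shows what the antibody and nuclease recover where the genotype label says that BCLAF1 is missing. An IgG library was not used here.

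The 2 HSC WT lists held 544 and 607 peaks and the HSC KO list held 4712. The native LSK list held 893 peaks and the fixed LSK list 289. On chromosomes 1 to 19, X and Y, which all comparisons use, these numbers were 447, 528, 4517, 770 and 278. Peaks were short, with median widths between 86 and 109 bp. The read background recovered from the peak statistics, which rises with sequencing depth, was 0.339 reads per position in HSC WT 1, 0.117 in HSC WT 2 and 1.15 in HSC KO. In native LSK cells it was 0.327, and in fixed LSK cells 0.022. The KO background was thus 3.38 times that of HSC WT 1, 9.80 times that of HSC WT 2 and 52.1 times that of the fixed LSK library. At these backgrounds the weakest called peak rested on 9 reads in HSC KO, 6 in HSC WT 1 and native LSK, 4 in HSC WT 2 and 3 in fixed LSK. With 1 library for KO, native and fixed cells, and 2 for HSC WT, no test across samples was run. Each test compares peak lists, not conditions.

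**Figure D1:**
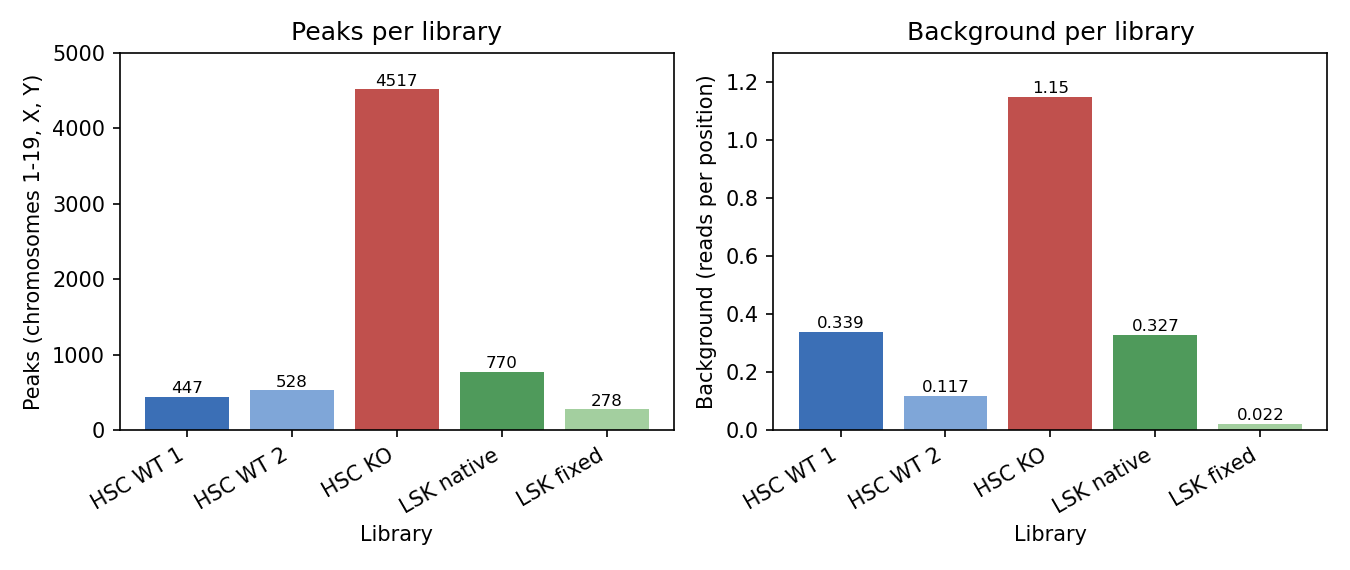
Peaks on chromosomes 1 to 19, X and Y (left, count) and recovered read background (right, reads per position) in each of the 5 libraries, 1 bar per library. HSC KO has the most peaks, 4517, and the highest background, 1.15, and fixed LSK has the fewest peaks, 278, and the lowest background, 0.022.

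The first comparison asked how far the 2 HSC WT libraries gave the same peaks. Of the 447 HSC WT 1 peaks, 279 overlapped a peak of HSC WT 2 (62.4%, exact 95% binomial interval 57.7 to 66.9). In the other direction 291 of 528 peaks overlapped (55.1%, 50.8 to 59.4). Random placement of the HSC WT 1 peaks on their own chromosomes gave a mean of 0.029 overlapping peaks (permutation p = 0.001, one-sided, the smallest that 1000 placements can give). The strongest shared region lay on chromosome X from 143482999 to 143483114, 35252 bp from Pak3, a p21-activated kinase gene, with an enrichment of 113 in HSC WT 1 and 114 in HSC WT 2. The next lay inside Chl1, a neural cell adhesion gene, on chromosome 6 from 103649064 to 103649292, with enrichments of 100.3 and 110.2. Enrichment is the authors' own value for each peak and is not scaled between libraries.

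Peaks also gathered in a few places. The 50-kb window with the most peaks lay at the start of chromosome 9 in every list, between positions 3000018 and 3038275. It held 58 peaks in HSC WT 1, 57 in HSC WT 2, 71 in HSC KO, 65 in native LSK and 18 in fixed LSK cells. That is 13.0% of the HSC WT 1 list and 1.57% of the KO list. Peaks within 10 kb of another made up 34.0% of HSC WT 1, against 0.474% on average after random placement. The share was 21.2% in HSC WT 2 against 0.553%, and 14.5% in KO against 4.14%. In native LSK cells it was 24.3% against 0.674%, and in fixed LSK cells 12.6% against 0.223%.

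The second comparison set the HSC WT peaks against the KO library, the control of the assay. Most WT peaks lay on KO peaks: 404 of 447 in HSC WT 1 (90.4%, exact 95% interval 87.3 to 93.0) and 350 of 528 in HSC WT 2 (66.3%, 62.1 to 70.3). Over both lists this was 754 of 975 peaks (77.3%). Random placement gave means of 0.204 and 0.197 overlapping peaks (permutation p = 0.001 for each list, one-sided; adjusted p = 0.001 over 20 pairs of lists). Peaks found in both WT libraries lay on KO peaks more often than peaks found in 1. In HSC WT 1 this held for 276 of 279 shared peaks (98.9%) and 128 of 168 others (76.2%; Fisher's exact test, two-sided, p = 1.58e-15). In HSC WT 2 it was 288 of 291 shared peaks (99.0%) and 62 of 237 others (26.2%; Fisher's exact test, two-sided, p = 2.62e-81). These tests and intervals count neighbouring peaks as independent. Without peaks within 10 kb of another of the same list, 158 of 172 shared peaks lay on KO peaks in each WT list (91.9%). Of the others, 61.8% did in HSC WT 1 and 23.0% in HSC WT 2. WT 2 peaks on KO peaks had a median of 11.5 reads and the others 4. When the 3 HSC lists were each held to their strongest 447 peaks, the size of the shortest, 46.5% of HSC WT peaks lay on KO peaks.

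**Figure D2:**
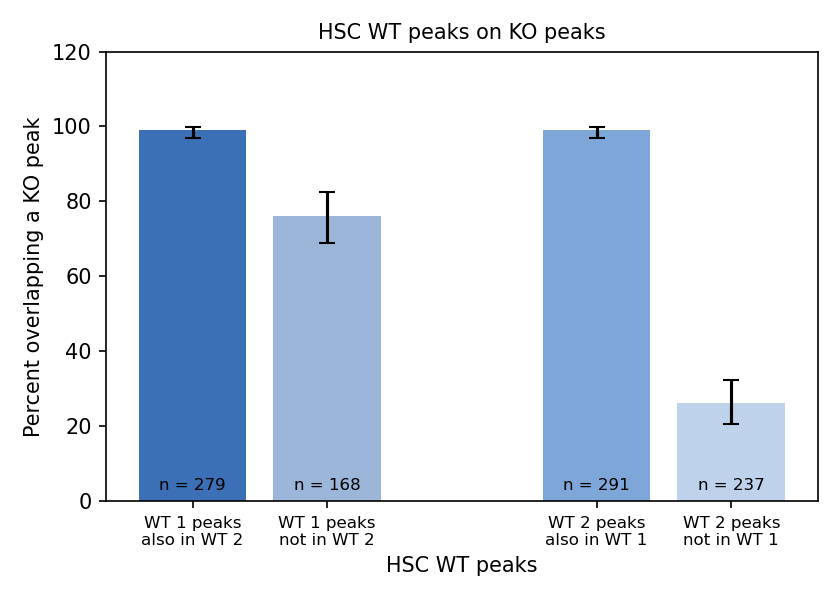
Percent of HSC WT peaks that overlap a KO peak by at least 1 bp, for peaks found in both WT libraries and for peaks found in 1; bars are percentages of the n peaks printed in each bar and error bars are exact 95% binomial intervals. Shared peaks stand at 98.9% and 99.0%, and the others at 76.2% in HSC WT 1 and 26.2% in HSC WT 2.

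Genes whose annotated boundary lay within 1 kb of a peak in both HSC WT lists and in KO were led by Wls, which encodes a carrier that brings Wnt proteins to the cell surface. Its peak, on chromosome 3 from 159939412 to 159939679, had an enrichment of 46.1 in HSC WT 1, 40.8 in HSC WT 2 and 64.1 in KO. Asmt, an enzyme of melatonin synthesis, had enrichments of 26.3, 13.0 and 43.7 in the same order. Lars2, a mitochondrial leucyl-tRNA synthetase, had 16.0, 10.4 and 33.4. Psmc3, a subunit of the proteasome, had 16.4, 7.87 and 68.1. Oasl1, an interferon-induced member of the oligoadenylate synthetase family, had 10.3, 6.27 and 31.1 at chromosome 5 from 114922458 to 114922552, 591 bp from the gene. The other members of this group were Gm32584, Spocd1, Gm21814, Adgb and Relt, with mean WT enrichments between 5.20 and 14.1. All these enrichments carry a pseudocount of 1, which lowers them most in the shallower WT libraries. Without it, reads over local background were 82.9, 88.8 and 69.2 at Asmt, in the same order of libraries. They were 40.1, 48.6 and 54.0 at Lars2 and 36.6, 51.3 and 50.9 at Oasl1. The KO reads at Wls and Psmc3 could not be resolved.

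Only 3 regions were called in both HSC WT lists and not in KO (1.08% of 279, exact 95% interval 0.222 to 3.11), and none lay within 1 kb of a protein-coding gene. The first lay on chromosome 17 from 28525997 to 28526072, 4789 bp from Armc12, with enrichments of 9.71 and 5.37 in the 2 WT libraries. The second lay on chromosome X from 40191136 to 40191210, 327532 bp from Cypt14, with 7.16 and 5.28. The third lay on chromosome 6 from 10085622 to 10085697, 836003 bp from Nxph1, with 5.98 and 4.37. In HSC WT 2 these peaks rested on 5, 5 and 4 reads, and none of the 3 regions had a peak in either LSK list. No region with at least 8 reads in both WT libraries lacked a KO peak. Without a minimum of reads, 78 shared regions lacked one when the 3 HSC lists were each held to 447 peaks. In that run 53.9% of HSC WT 1 peaks were shared with HSC WT 2. Without peaks that lay within 10 kb of another of the same list, the count was 14 of 172 shared peaks. As shares, both lay above the interval given for all peaks. With 1 WT library alone the count without a KO peak was 43 in HSC WT 1 and 178 in HSC WT 2.

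The KO list held 4069 peaks that overlapped no HSC WT peak (90.1%). Among those within 1 kb of a gene boundary, the strongest lay at Ubtfl1, with an enrichment of 37.9, and Cand2, a cullin-associated protein, with 32.6. Both also had a peak in native LSK cells, at 17.0 and 8.29. Next came Tyk2, a kinase of interferon receptors, with 23.3, Cab39, a partner of the LKB1 kinase, with 19.6, and Tex30 with 19.4. Tm7sf3, Itgb2l, Galm, Jsrp1 and Meis1, a transcription factor of stem cells, lay between 16.3 and 17.7. These 8 had no peak in the other 4 lists. Chromosome Y held 556 KO peaks, against 27 in HSC WT 1 and 19 in HSC WT 2. As shares of all deposited peaks these were 11.8%, 4.96% and 3.13%. In native LSK cells the share was 6.38%, and in fixed LSK cells 2.08%.

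Bclaf1 itself, on chromosome 10 from 20310512 to 20342644, and its paralog Thrap3, on chromosome 4 from 126164082 to 126202755, had 0 peaks within 5 kb in every list. Peak lists of this kind hold no value for the expression of the targeted gene, so the KO label could not be checked from them.

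The third comparison set fixed against native LSK cells. Of the 278 peaks of the fixed library, 82 overlapped a native peak (29.5%, exact 95% interval 24.2 to 35.2), against a mean of 0.030 after random placement (permutation p = 0.001, one-sided, adjusted p = 0.001). Among fixed peaks that lay on a KO peak, 78 of 96 overlapped a native peak (81.3%). Among the rest 4 of 182 did (2.20%; Fisher's exact test, two-sided, p = 6.84e-46). Peaks found in the fixed library alone numbered 177 (63.7%), and 121 of them rested on 3 reads. The share of fixed peaks that overlapped a native peak, 29.5% with all peaks, depended on which peaks were counted: it was 60.7% for peaks with a −log10 q of at least 5, 16.2% for lists of equal size and 9.26% without the regions called in all 5 lists.

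The 5 regions of both LSK lists to be named were taken by the mean of the 2 enrichments, which are not on a common scale. One lay on chromosome 12 from 3109870 to 3110117, 137311 bp from Rab10, with enrichments of 79.9 in native and 101 in fixed cells. The Chl1 region had 106 and 55.3. A region inside Dpp9, a dipeptidyl peptidase gene, on chromosome 17 from 56200002 to 56200091, had 41.1 and 105. The Pak3 region had 118 and 20.5. A region 14707 bp from Pla2r1, on chromosome 2 from 60402759 to 60402836, had 33.1 and 93.4. All 5 were also called in KO. The genes within 1 kb of a peak in both LSK lists were Wls, at 55.2 in native and 5.79 in fixed cells, and Lars2, at 21.8 and 14.1. Those with the strongest peak in native cells alone of the 2 were Adgb (29.4), Psmc3 (23.8), Asmt (23.0), Oasl1 (20.2) and Stc2, which encodes stanniocalcin 2 (18.9). Those in fixed cells alone were Dcpp2, with an enrichment of 4.86 from 4 reads, and Hlf, S100a7a, Afp and Pygm, each from 3 reads. Hlf is a stem cell transcription factor and Afp the alpha-fetoprotein gene of fetal liver.

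Of the 8 regions called in at least 2 lists but not in KO, 4 were in both LSK lists. They lay inside Camk2b (chromosome 11 from 6006254 to 6006580), inside Thy1, a surface antigen gene (chromosome 9 from 44046657 to 44046904), 3820 bp from Tubb3 (chromosome 8 from 123425835 to 123425955) and 8797 bp from Def8 (chromosome 8 from 123434040 to 123434159). In native cells their enrichments were 17.8, 7.40, 19.6 and 19.3, and in fixed cells 13.9, 7.51, 27.7 and 20.3. None was called in an HSC WT list. These 4 regions were chosen after their values were seen.

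The fourth comparison set LSK cells against HSCs. Of the 770 native LSK peaks, 375 overlapped a peak of either HSC WT library (48.7%, exact 95% interval 45.1 to 52.3; permutation p = 0.001 against each WT list, one-sided). More of them, 650, lay on HSC KO peaks (84.4%, 81.7 to 86.9), but that list held 4517 peaks against 447 and 528 in the HSC WT lists. The share on KO was not computed at equal list sizes. All 375 native peaks shared with HSC WT also lay on a KO peak. Of the 120 native peaks without a KO peak 0 overlapped an HSC WT peak (Fisher's exact test, two-sided, p = 5.26e-40). Those 120 were also weaker, with a median enrichment of 6.03 against 9.79 for native peaks on KO peaks. Across the 5 lists the peaks merged into 5029 regions. Of these 4290 (85.3%) were called in 1 list, 3783 of them in KO, and 58 (1.15%) in all 5. Another 188 regions were called in both HSC WT lists, KO and native LSK cells.

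**Figure D3:**
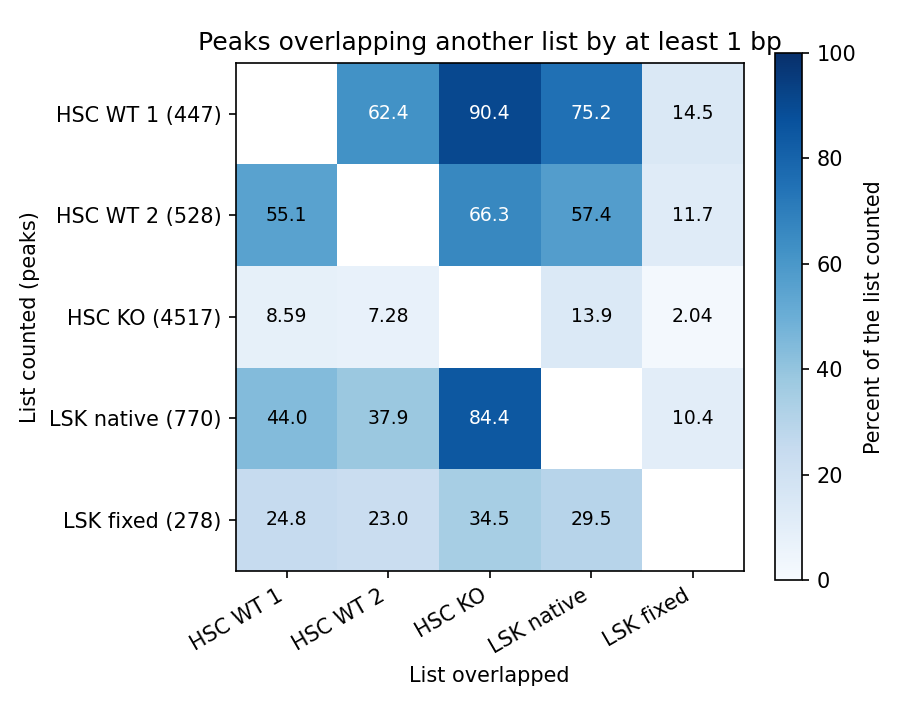
Percent of each list's peaks (rows, number of peaks in parentheses) that overlap a peak of each other list (columns) by at least 1 bp. The highest shares are 90.4% of HSC WT 1 peaks and 84.4% of native LSK peaks on peaks of HSC KO, the longest list.

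Peaks were then placed relative to 21883 protein-coding genes. Between 2.52% (fixed LSK) and 3.60% (HSC WT 2) of the peaks lay within 1 kb of a gene boundary. In no list did the share differ from random placement (two-sided permutation, lowest adjusted p = 0.839 over 5 lists), and no pair of lists differed (Fisher's exact test, adjusted p = 1 over 10 pairs). For both HSC WT lists together the share was 3.49%, against 3.17% after random placement (two-sided permutation p = 0.595). Within 5 kb the direction turned: 9.23% of HSC WT peaks lay there against 12.4% after random placement (two-sided permutation p = 0.00399, the smallest possible in that run). Fewer peaks lay inside genes than after random placement in 4 lists: 22.6% against 38.8% in HSC WT 1, 27.3% against 39.4% in HSC WT 2, 29.3% against 35.6% in KO and 27.5% against 37.9% in native LSK (two-sided permutation, p = 0.002, the smallest possible, adjusted p = 0.0025 each). In fixed LSK cells 35.6% lay inside genes against 39.7% (two-sided permutation, adjusted p = 0.168). These 4 shares stayed below random placement without the crowded window of chromosome 9 (two-sided permutation, highest adjusted p = 0.005). Without all peaks within 10 kb of another the gap narrowed, to 30.8% against 37.7% in HSC WT 1 and 32.8% against 37.0% in native LSK (two-sided permutation, highest adjusted p of the 4 = 0.0325). Pairs of lists were compared by Fisher's exact test, two-sided, which counts neighbouring peaks as independent. The share was higher in fixed LSK than in HSC WT 1 peaks (Fisher's exact test, adjusted p = 0.00167), HSC WT 2 peaks (0.0387) and native LSK peaks (0.0387), and lower in HSC WT 1 than in KO (0.0127). Without that window only the first of these passed (Fisher's exact test, adjusted p = 0.0131, 0.102, 0.0664 and 0.232 in the same order), and without peaks within 10 kb of another none did. Fixed LSK against KO passed in both of these runs (Fisher's exact test, adjusted p = 0.0272 and 0.0332) but not with all peaks (0.0606).

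**Figure D4:**
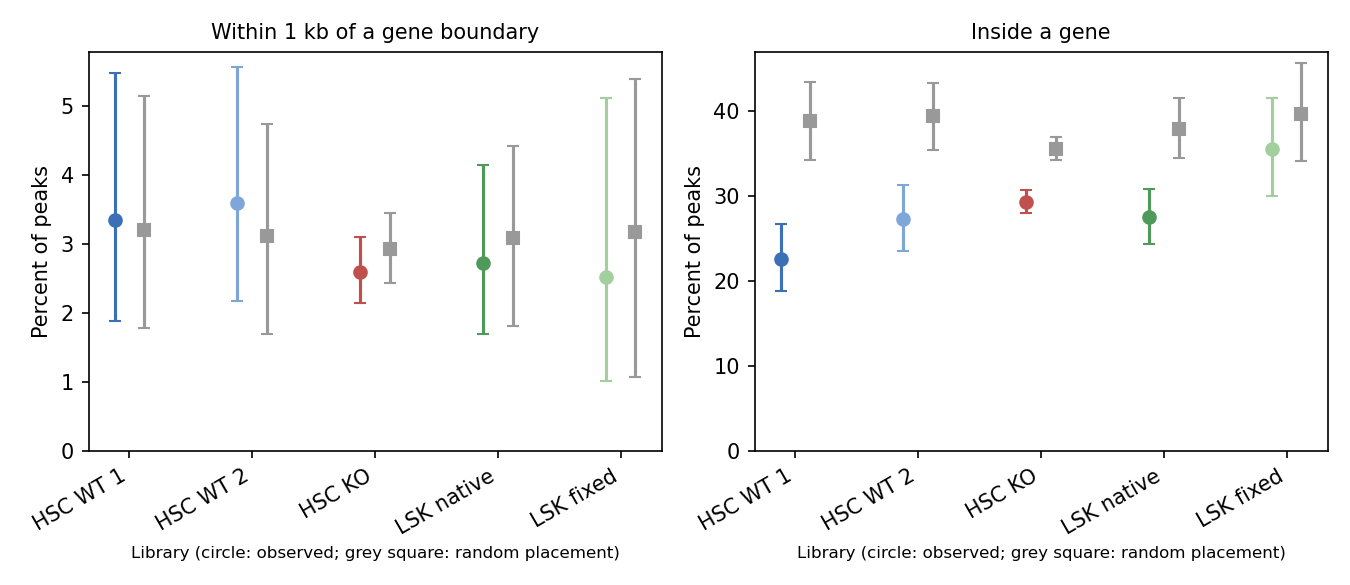
Percent of each library's peaks within 1 kb of a protein-coding gene boundary (left) and inside a gene (right). Circles are observed shares with exact 95% binomial intervals, and grey squares are means of 1000 random placements with the range of their central 95%; inside genes, the observed share of HSC WT 1 is 22.6% against 38.8% after random placement.

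The last comparison asked which gene groups had a peak within 1 kb of a gene boundary. Of the 80 tests of 16 gene lists in 5 libraries, 0 passed after adjustment (Fisher's exact test, two-sided, lowest adjusted p = 0.382). At an unadjusted p under 0.05 there were 6 of the 80, each resting on 1 or 2 genes. Among 38 interferon response genes, Oasl1 was the only one with such a peak in HSC WT 1, HSC WT 2 and native LSK cells. In KO it was joined by Tyk2 (Fisher's exact test, unadjusted p = 0.0179; adjusted p = 0.476). Adjusted over the list alone, the interferon response list passed in these 4 libraries (Fisher's exact test, adjusted p = 0.0448), the KO library included. In fixed LSK cells the HSC identity list had Hlf and the hepatocyte list Afp (Fisher's exact test, adjusted over the list alone, p = 0.0478 and 0.0319), each a peak of 3 reads. The KO list also held Meis1 of the HSC identity list and Hspa4 of the heat shock and integrated stress list. Another 11 lists had 0 genes with such a peak in all 5 libraries. They covered NF-kB and inflammation, p53 and apoptosis, the DNA damage response, immediate early genes, splicing factors, cytosolic ribosomal proteins, the cell cycle, replication-dependent histones, and myeloid, lymphoid and megakaryocyte genes.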

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

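All tests of explanations were chosen after the peak lists had been compared and the patterns seen. For those of chromosome Y, of regions that gather reads, of chance placement at stem cell genes and of fixation, the values they measure had also been seen.

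One unplaced sequence outside the compared chromosomes held more peaks in a WT library than in the KO library: GL456387.1 had 1 peak in native LSK cells, with an enrichment of 5.02, and 0 in HSC KO.

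The HSC KO list held 4517 peaks against 447 and 528 in the HSC WT lists. Depth accounts for part of this at most: after KO reads were thinned to the background of HSC WT 1, a mean of 1968 peaks would still be called, 4.40 times that list (range over 100 draws 4.28 to 4.55), and at the background of HSC WT 2 the ratio was 1.71. Chromosome Y is not the source either, since 3961 KO peaks lay elsewhere. Thinned to the background of native LSK cells, the KO list stayed 2.43 times as long, while at the background of fixed LSK cells it was shorter than theirs, at 0.670 times (0.608 to 0.770). Loss of BCLAF1 may be involved, but with 1 KO library it cannot be told apart from other properties of that library, such as its signal over background, duplicate reads or the embryos in its pool. The thinning takes background as the measure of depth and leaves 88 of the strongest peaks as called.

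Of the HSC WT 1 peaks shared with HSC WT 2, 276 of 279 lay on KO peaks. Chance overlap within neighbourhoods is argued against for the list as a whole. Of 1000 random shifts of all 447 HSC WT 1 peaks by up to 50 kb, the highest put 29 on KO peaks. Observed were 404 (permutation p = 0.001, the smallest possible). Such shifts can carry peaks out of the crowded window of chromosome 9, so chance overlap inside it is not excluded. Without that window 224 of 227 shared peaks lay on KO peaks. Whether the 276 regions gather reads in any library stays open for the set. Of them 92.0% also had a peak in native LSK cells but 58 of 276 in the shallower fixed LSK library. Sites bound in both WT cell types would be shared too. In the chromosome 9 window, the densest of all 5 lists, reads did gather. At 3004105 to 3004260, for example, the local background was 388 reads per position in HSC WT 1, 162 in HSC WT 2 and 719 in KO. The genome backgrounds were 0.339, 0.117 and 1.15. Residual BCLAF1 in the KO cells stays open. Reads over local background were 0.952 times those of KO at the median region in HSC WT 1 (bootstrap 95% interval 0.891 to 0.999). In HSC WT 2 they were 1.20 times those of KO (1.14 to 1.24). Every region had to be called in both WT lists. The weakest calls were 4 reads over 0.117 in HSC WT 2, 6 over 0.339 in HSC WT 1 and 9 over 1.15 in KO. This selection can raise the WT values, most in HSC WT 2. The bootstrap takes regions as independent, though neighbouring regions can share the same KO peak, so its intervals are likely too narrow. The HSC WT 1 interval reached 1.04 over the genome background, and 82 of the strongest regions could not be resolved. Values under 1 in 1 library therefore decide nothing, nor do values above 1 in the other.

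In fixed LSK cells 4 peaks lay inside or within 10 kb of genes of the HSC identity list: 2 in Runx1, 1 in Mecom and 1 in Hlf, against 0.371 expected from random placement (permutation p = 0.0014, one-sided). Chance is not excluded, since over the 80 list and library pairs the adjusted p was 0.112 (adjusted over the list alone, 0.007) and the test followed the sight of Runx1 and Mecom among the strongest peaks of that list. The other 4 lists, all of higher background, had no peak at these positions, though HSC WT 2 had another inside Mecom, of 4 reads. At the same ratio to background, the weakest of the 4 HSC identity peaks would have 44.6 reads in native LSK cells (exact Poisson lower bound 9.20). There 6 sufficed for a call. This outcome was fixed in advance, since 3 reads, the fewest behind any called fixed peak, already lead to it. The comparison therefore cannot tell sites missed in native cells from noise in the fixed library. Fixation stays open: the share of peaks at these genes was 5.54 times that in native cells (4 of 278 against 2 of 770), which restates what prompted the test, and with 1 library each it cannot be told apart from the library. Duplicate reads of few fragments stay open as well, and since a fixed KO library was not analysed here, whether these peaks need BCLAF1 was not tested.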

How the results depend on the processing

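Chosen after seeing the data were the minimum of 8 reads, the shifts of up to 50 kb, the removal of peaks within 10 kb of another, the removal of the chromosome 9 window, the thinned KO list and the 10-kb gene test. The placement p of the 4 overlap results was at its floor, 0.005 for 200 permutation placements, in every run, and so says nothing about stability. Their values ranged from 53.9% to 66.7% for HSC WT 1 peaks on HSC WT 2, from 46.5% to 96.8% for HSC WT peaks on KO, from 9.26% to 70.4% for fixed LSK peaks on native, and from 37.9% to 62.6% for native LSK peaks on HSC WT. With 1 HSC WT library left out, the share on KO lay between 66.3% and 90.4%. The count of gene list calls was 0 under all 6 alternatives, with lowest adjusted p between 0.112 and 1 (Fisher's exact or permutation test).

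The count of shared HSC WT peaks without a KO peak, 3, became 24 when 0.5 of the length of both peaks had to overlap, 1 at a −log10 q of at least 5, 78 with lists of equal size, 14 without peaks within 10 kb of another, 0 with at least 8 reads and 12 with the thinned KO list (9 to 15 over 50 draws). Lists of equal size and the removal of crowded peaks keep fewer KO peaks and the longer overlap drops partial matches. With 1 HSC WT library left out, the count of its partner's peaks was 43 to 178. The placement that keeps the share near genes was not run for this count, which has no placement test.

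The share of HSC WT peaks near genes, 3.49% within 1 kb and above its random mean, fell below the random mean within 5 kb (9.23% against 12.4%, permutation p = 0.00399, the smallest possible there), within 200 bp (0.513% against 0.830%, p = 0.331, permutation) and at a −log10 q of at least 5 (3.00% against 3.18%, p = 0.914, permutation). The cause was not tested. The share inside genes in HSC WT 1 against KO, 22.6% (Fisher's exact test, adjusted p = 0.0127), was 26.0% without the chromosome 9 window (Fisher's exact test, adjusted p = 0.232), and at 30.8% above KO without peaks within 10 kb of another (Fisher's exact test, adjusted p = 0.948). HSC WT 2 then stood above KO, at 30.6% and 31.7% (Fisher's exact test, adjusted p = 0.897 and 0.935). Native LSK cells, at 30.1% and 32.8%, no longer passed against fixed cells (Fisher's exact test, adjusted p = 0.0664 and 0.136). Against fixed LSK peaks, HSC WT 1 at 30.8% no longer passed without peaks within 10 kb of another, nor did HSC WT 2 in either run (Fisher's exact test, adjusted p = 0.115, 0.102 and 0.115), while KO, at 29.8% and 30.6%, came to pass (Fisher's exact test, adjusted p = 0.0272 and 0.0332). The window's peaks lay outside genes, since HSC WT 1 had 101 peaks inside genes with and without it. At least 8 reads were behind 81 of the 278 fixed LSK peaks and 249 of the 528 HSC WT 2 peaks, against 408 of 447 in HSC WT 1; what depth alone limits was not separated from other properties of these libraries.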

Other observations

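The gene groups were also looked at over whole genes with 10 kb on either side, a test chosen after seeing the data. In HSC KO, Meis1 had 3 such peaks and Erg 1, both stem cell transcription factors, and the 4 peaks of the HSC identity list stood against 5.51 expected from random placement (permutation p = 0.802, one-sided). The Erg peak, on chromosome 16 from 95504017 to 95504083, was also called in native LSK cells, which had another inside Etv6. In HSC WT 2 the one peak of this list lay inside Mecom, on chromosome 3 from 30374984 to 30375074, with 4 reads and in no other list. A region near Tra2a, a splicing factor, on chromosome 6 from 49236473 to 49236596, had a peak in every list except HSC WT 2, with enrichments of 16.8 in HSC WT 1, 26.9 in KO, 13.3 in native and 6.61 in fixed LSK cells. Near Hba-a2, an alpha-globin gene, a peak was called in KO at 13.5 and in native LSK cells at 6.78. The splicing factor list had 2 peaks in fixed LSK cells, near Tra2a and Sf1, against 0.167 expected (permutation p = 0.0124; adjusted p = 0.443 over 80 tests). The Sf1 peak, of 3 reads, is the same peak as the one named at Pygm.

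In fixed LSK cells the 4 regions of both LSK lists with the highest enrichment in the fixed library lay inside Dpp9 (105), 137311 bp from Rab10 (101), 99585 bp from Gm8882 (96.9) and 14707 bp from Pla2r1 (93.4). The strongest peak found in the fixed library alone lay on chromosome 14 from 107075300 to 107075378, 939438 bp from Trim52, with an enrichment of 58.7 from 102 reads. The next lay inside Ano2 on chromosome 6 from 125876911 to 125877108, with 45.4 from 77 reads. The Runx1 peaks lay on chromosome 16 from 92644182 to 92644341 and from 92695532 to 92695737, with 12 reads each, and the Mecom peak on chromosome 3 from 29986246 to 29986328, with 11. A region on chromosome 6 from 10186383 to 10186461, 936764 bp from Nxph1, was called in HSC WT 2 at 18.7 and in fixed LSK cells at 61.2, and not in KO.

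Of 19 unplaced or mitochondrial sequences with a peak in any library, 9 had one in all 3 HSC libraries. The unplaced sequence JH584304.1 held 74 peaks in HSC WT 1, 65 in HSC WT 2, 111 in KO, 95 in native and 8 in fixed LSK cells. On GL456396.1 the highest enrichment was 88.8 in HSC WT 1, 96.3 in HSC WT 2 and 70.0 in KO, and on GL456389.1 it was 67.4, 72.3 and 49.8. Both WT values were above KO on 3 of the 9 sequences and both below on 3, such as GL456370.1 with 65.9, 34.8 and 86.6. These values are not scaled between libraries.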
